A study of Equus caballus with 18 samples.

How the data were processed

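Genomic DNA was isolated from white blood cells and 4 ug was labelled, per the labels' protocols, and test and reference DNA were co-hybridised to Agilent arrays with Cy5 for the test animal and Cy3 for the reference. Per the submitters' processing notes, images were read with Agilent Feature Extraction 10.7.1.1. The deposited scanner files give each spot's processed intensity, background-subtracted and dye-normalised per array by the software per the file headers, where the linear dye factors are given and the lowess factors are 0. They also give the median intensity of spot and local background, with no correction. The deposited value table of the series holds log10 ratios equal to the scanner files' own log ratio, with a largest difference of 0, so its scale (log10 of red over green) and direction are known, and it is not centred further. Its column medians ran from -0.00291 to 0.0134. The log2 ratio used here is the authors' processed red signal over their processed green signal. The genome build of the probe coordinates is not given in the sources used here.

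Control spots and spots that the software marked as outliers were left out, and so were probes that were dim (not well above background) in the red and also in the green channel. This kept 405850 to 418333 of 418576 probes per array (97.0% to 99.9%), and no probe was saturated. A total of 3956 probes are written with their end before their start and were turned. Each array was centred on the median of its autosomal probes, a shift of at most 0.06, with no loess or quantile step. Noise was the median absolute difference of neighbouring probes, scaled to an SD. A single probe more than 4 SD beyond its 2 neighbours on each side was drawn in to 2 SD from their median.

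Calls were intervals of consecutive probes of a chromosome with an interval score (absolute sum of log2 ratios over the noise times the square root of the number of probes) of at least 6, at least 5 and at most 1000 probes, and a mean and median of at least 0.3 in size. X probes were centred on their own median before calling. Calls of the 14 horses sharing at least 1 probe formed a region. A region's value in an array is the mean over all its probes, so it lies nearer to 0 than the calls inside a wide region. Tested on simulated data, the caller made 0 calls in Gaussian noise over 400281 probes, and with planted intervals it found 100% of those of 5 probes at -1, 52.9% of those of 5 probes at -0.6 and 0% of those of 5 probes at 0.4. In the self comparison with planted intervals it found 29.4% of those of 10 probes at 0.4 and 93.8% of those of 30 probes at 0.4. Changes of 0.4 over 5 probes are therefore missed.

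Tests across the genome used limma 3.58.1 in R 4.3.3 (lmFit, eBayes with trend, Benjamini-Hochberg adjustment, statmod 1.5.0 for block correlations) on means of 10 consecutive probes with at least 3 measured, in blocks with values in at least 8 arrays. Blocks stand in for genes because the files name none. For the same reason the 14 gene lists fixed before the data were examined and their enrichment tests were not run. With trend, the standard errors of the chromosome 7 blocks are larger than their own spread alone would give. Tested on simulated data with 200 changed blocks among 40013, by 0.5 and 1 in size for the horses and 1.5 and 3 for the donkey, the fit of 14 horses against 0 recovered 100% with 0 false calls, and the fit of the donkey against the horses 98% to 100% with 2 false calls. Recovery of smaller differences, down to the 0.3 at which blocks were called, was not simulated. The simulated values were independent between arrays, with unchanged blocks at a mean of 0. They held no dye profile and no correlation within slides or scan runs (0.176 and 0.481 in the data). The counts of false calls therefore do not carry over to the real arrays. Other tests were exact binomial tests, exact permutation tests and permutation tests with 100000 draws, all two-sided, in Python 3.11.15 with scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and numba 0.67.0.

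The 18 arrays form a group of 14 horses against the Thoroughbred and 4 single arrays. Each breed has 1 animal among the 14 horses, and the horse set against Twilight shares its breed with 1 of them. No breed was tested, and p-values over the horses measure the spread between these animals. The arrays came from 6 slides, 4 of them scanned in 2 runs, which makes 10 scan runs. On these 4 slides the recorded slide and array position is the same for different comparisons in the 2 runs. The Arabian and the donkey, for example, share a position, with green signal over noise of 98.0 and 20.1. Whether these arrays were used again is not given in the sources used here. The rule for named regions, fixed before the data were examined, took the 10 regions with gains and the 10 with losses called in the most horses, the 5 calls of highest score per direction in the single arrays, and the 10 highest and 10 lowest blocks; beyond it, regions are said to be chosen after their values were seen.

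Alternatives fixed before the data were examined were a score of 8, at least 10 probes, a size of 0.5, normexp background correction with an offset of 50, the value table, subtraction of the self comparison, no filter on dim probes, centring on all probes, no smoothing, a hidden Markov model with states at 0.5 in size, 50% reciprocal overlap for regions, medians over probes, no minimum size, slide as a random block, Spearman's rho and pairs on different slides. Normexp was run on median spot signals, because the files used here hold no mean signals. Alternatives chosen after seeing the data were a correction for probe length, that correction with the scaled local profile of the self comparison, leaving out calls over same-direction calls of the self comparison, leaving out the Hanoverian and Curly arrays (picked for their many calls or their strong trend with probe length), scan runs in place of slides, and slide or scan run as a fixed block. The score of 40 for further loci, the size of 0.2 for the self comparison and the relations of calls, gains and losses with probe length and signal, pooled, within slides and across scan-run means, were also set after the data had been looked at.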

Results

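Copy number along the horse genome was measured on 18 arrays, each carrying 418576 probes with a median length of 50 bp on autosomes 1 to 31 (400281 probes) and the X chromosome (18295 probes). Genomic DNA from white blood cells of a test animal and of a reference animal shared each array in different dyes, and every value is the log2 ratio of test over reference. A positive ratio is a gain of the test animal relative to the reference animal, or equally a deficit of the reference. In 14 arrays a horse of a named breed was set against 1 Thoroughbred, with 1 animal per breed. Single arrays held a donkey against that Thoroughbred, the Thoroughbred against itself, the Thoroughbred against Twilight (the animal whose DNA gave the reference genome assembly) and another horse against Twilight, whose breed is also that of 1 of the 14 (its breed mate). Red signal over noise ran from 12.6 in the donkey to 57.5 in the Paso Fino, and the probe-to-probe noise of the log2 ratio from 0.18 to 0.33. Each comparison was made on 1 array and no dyes were swapped. Values of a single array therefore carry no replicate error, and the number of arrays limits the precision. The files pair no probes with genes, so positions are given in the coordinates of the array design, whose genome build is not given in the sources used here.

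The Thoroughbred hybridised against itself shows how many intervals are called where both channels hold the same DNA. It gave 497 autosomal calls, 272 gains and 225 losses. Its strongest gain, at chromosome 1:78747161-78751734, averaged 0.52 ± 0.15 (SD over 50 probes), and the median of the 14 horses there was 0.58. At chromosome 7:47907032-48405457 the self comparison averaged 0.45 and the median of the horses was 0.51. Its strongest loss, at chromosome 6:9060519-9063200, averaged -0.91 ± 0.55 (SD over 11 probes), against a median of -0.17 in the horses. Calls of the self comparison fell to 137, 115 gains and 22 losses, when an interval score of 8 was required in place of 6.

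The 14 breed arrays ask where horses differ in copy number from the Thoroughbred. They held 9580 autosomal calls, 5895 gains and 3685 losses. The Arabian had the fewest calls (172), followed by the Andalusion (184) and the Welsh Arabian Pony (194), and the median horse had 672.5. The Hanoverian had 1898 calls, 19.8% of all, with 1082 losses. Gains made up 83.5% of the calls in the Peruvian and 28.1% in the Gypsy Vanner. In total 2804 calls (29.3%) overlapped a call of the self comparison in the same direction, from 3.49% in the Arabian to 54.7% in the Lusitano. With the self comparison subtracted probe by probe and calls made anew, there were 3808 calls and gains made up 44.7% of them, against 61.5% without subtraction. The share of a horse array's variance that went with probe length ran from 0.498% in the Andalusion to 29.4% in the Hanoverian, so counts of calls do not rank the breeds. The order of the horses turned with the processing: with normexp background correction the Arabian had 542 calls, the Welsh Arabian Pony 510, the Hanoverian 460 and the Andalusion 90, and with the self comparison subtracted these were 506, 286, 487 and 359.

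**Figure D1:**
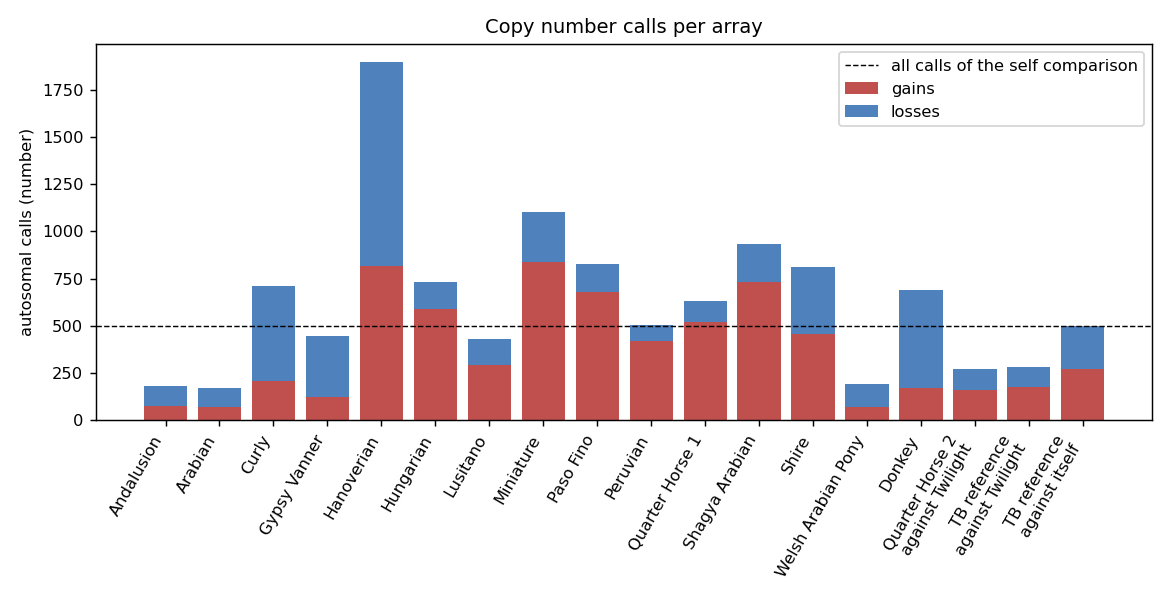
Number of autosomal copy number calls (vertical axis) in each of the 18 arrays, with gains in red and losses in blue. The dashed line marks the 497 calls of the Thoroughbred against itself; the horses run from 172 to 1898 calls.

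Calls of the 14 horses that shared a probe were merged into 3288 regions, of which 1291 held only gains, 1897 only losses and 100 both. A total of 1589 regions were called in at least 2 horses and 171 in at least 10. Without the Hanoverian and Curly arrays 30 were called in at least 10 of the other 12 horses, and regions gained in at least 10 went from 145 to 12. The cutoff of 10 was kept with fewer arrays, so part of this fall follows from the larger share required. No other pair of arrays was left out, so the fall is not tied to these arrays. A pair of neighbouring regions on chromosome 20 were gained in all 14 horses. At 27711496-27727495 the horses averaged 0.88 ± 0.14 (SD, n = 14) and at 27768613-27836391 they averaged 0.65 ± 0.11 (SD, n = 14). In both the self comparison was near 0 (0.07 and -0.01), and the Thoroughbred against Twilight had the opposite sign (-1.05 and -0.65). The donkey lay among the horses there, at 0.85 and 0.66.

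Chromosome 5:37778431-37954145 was called as a gain in all 14 horses and as a loss in 1, with a mean of 0.42 ± 0.47 (SD, n = 14) over the whole region, where the self comparison also held a gain call and lay at 0.21. The loss belonged to the Peruvian, in which 33 probes at 37888905-37954145 averaged -2.62 ± 1.55 (SD over probes), a bound, since 23.5% of its probes there were well above background in the red channel. In the same interval the Hungarian, Paso Fino and Shagya Arabian lay at 0.05, 0.10 and 0.18, and the other horses between 0.63 and 0.89. Chromosome 6:66028850-66149160 was gained in 13 horses and lost in the Hungarian. Over 11 probes at 66088840-66103496 the Hungarian lay at -3.45, a bound with 36.4% of its red probes well above background, and the other horses between 0.73 and 0.95, with the Thoroughbred against Twilight at -0.93. Chromosome 5:21915310-21950293 was gained in 13 horses, with a mean of 0.62 ± 0.26 (SD, n = 14), while the donkey lay at -2.79. On chromosome 15, the regions at 28887998-28961807 and 29246709-29341492 were gained in 12 horses each, with means of 0.44 ± 0.24 and 0.35 ± 0.21 (SD, n = 14) and values of -0.37 and -0.36 in the Thoroughbred against Twilight. Chromosomes 3:65434843-65753594 and 22:23876382-24238588 were also called in 12 horses, but their whole-region means were 0.17 ± 0.10 and 0.15 ± 0.12 (SD, n = 14).

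Among regions with losses, 4 were called in all 14 horses. Chromosome 1:132480314-132502473 averaged -0.80 ± 0.14 (SD, n = 14), with 0.41 in the Thoroughbred against Twilight and -0.01 in the self comparison. Chromosome 3:43548122-43617913 averaged -0.52 ± 0.04 (SD, n = 14) and kept a negative sign in the Thoroughbred against Twilight, at -0.38. Chromosome 6:68390764-68408460 averaged -0.56 ± 0.14 (SD, n = 14), and the self comparison gave -0.61 there, so the horses did not lie below this background. Chromosome 20:30616719-31231144 averaged -0.37 ± 0.10 (SD, n = 14), with -0.24 in the self comparison.

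The regions at chromosome 8:494261-760293 and chromosome 1:110384223-110556286 were lost in 13 horses each. Their means were -0.45 ± 0.17 and -0.52 ± 0.13 (SD, n = 14), and the Thoroughbred against Twilight had the opposite sign in both (0.47 and 0.28). A region of 2561.5 kb at chromosome 12:12310441-14871949 held losses in 13 horses and gains in 8, with horses between -1.06 and 0.24. Losses in 11 horses each were called at chromosome 13:31510375-31887880 (-0.62 ± 0.30), chromosome 20:24252156-24608527 (-0.39 ± 0.26) and chromosome 21:53922759-56389317 (-0.24 ± 0.10), where each value is a mean ± SD over 14 horses. The chromosome 20 region lay at 0.81 in the Thoroughbred against Twilight, and the other regions at -0.10 and -0.02.

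On chromosome 7, the region at 73056838-73699307 was gained in 12 horses and lost in 5. Over up to 309 measured probes at 73361042-73699307, the Andalusion and the Gypsy Vanner reached 3.43 and 3.42, the Arabian 3.05, the Shagya Arabian 3.01, the Lusitano 2.80, the Hanoverian 2.77, the Paso Fino and the breed mate of the horse set against Twilight 2.59 each, the Welsh Arabian Pony 2.43, the Peruvian 2.31 and the Curly 2.11. The Miniature averaged 1.28 over the whole interval and 2.76 over its part at 73592740-73679261. The Hungarian (-0.17) and the Shire (-0.18) lay close to the self comparison (-0.12), over the 240, 157 and 154 probes that were measured in these 3 arrays. The donkey lay at 3.45, the Thoroughbred against Twilight at -3.44 and the horse set against Twilight at 0.00. The signal of the Thoroughbred in the green channel was well above background for a median of 51.1% of these probes, and that of Twilight for 100%, so the sizes of the ratios over the Thoroughbred are bounds set by background. So is the ratio of the Thoroughbred over Twilight, with 35.9% of its red probes well above background. Upstream, at 73078621-73342083, the Gypsy Vanner (-0.77) and the Miniature (-0.82) were low and the other 12 horses lay between -0.02 and 0.20.

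**Figure D2:**
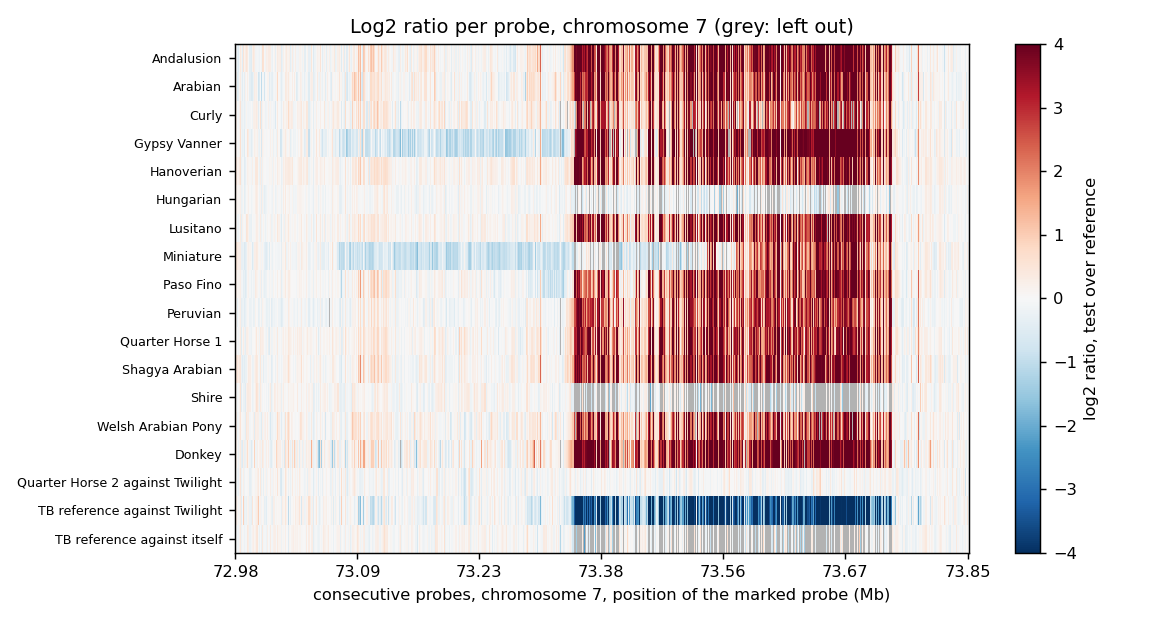
Log2 ratio of test over reference (colour) at consecutive probes of chromosome 7 (horizontal axis, position in Mb of marked probes) in the 18 arrays (vertical axis), with grey for probes left out. The ratio turns from 3.45 in the donkey to -3.44 in the Thoroughbred against Twilight, and the Hungarian and the Shire stay near -0.17 and -0.18.

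Other loci came from calls with an interval score of at least 40 outside same-direction calls of the self comparison, a rule chosen after the values were seen; it leaves out the chromosome 7 loss of the Thoroughbred against Twilight, which overlaps a loss in the self comparison. Several of them separated the horses into distinct levels. At chromosome 1:155360741-155640247, the Shire lay at -2.52, the Lusitano at -0.57 and the horse set against Twilight at -0.65, and the other 12 horses between -0.08 and 0.18. Only 61% of the probes of the Shire were well above background there, so its value is a bound. At chromosome 6:71977973-72544728 the Shire (-0.69), Andalusion (-0.60), Welsh Arabian Pony (-0.58), Lusitano (-0.56) and Paso Fino (-0.53) were low and the other 9 horses lay between -0.08 and 0.20. The loss of the Shire ran on to 73390643. At chromosome 25:26274736-26980247 the horse set against Twilight (-0.79) and its breed mate (-0.76) were low, as were the Hungarian (-0.73) and the Welsh Arabian Pony (-0.64), while the other 11 horses lay between -0.11 and 0.02.

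Short loci showed 3 levels. At chromosome 13:39573372-39594524 (22 probes) the Lusitano (-2.89) and Andalusion (-2.84) were lowest, the Gypsy Vanner, Arabian, Hanoverian, Miniature and Shagya Arabian lay between -0.87 and -0.69, and the other horses between -0.05 and 0.03. At chromosome 25:35494492-35517479 (18 probes) the Gypsy Vanner and Hanoverian (-2.75 each) and the Welsh Arabian Pony (-2.27) were lowest, 6 horses lay between -0.94 and -0.66, and the other 5 between -0.04 and 0.04. At chromosome 30:26250599-26262885 (8 probes) the Gypsy Vanner (-3.95), Miniature (-3.65), Hungarian (-3.26), Andalusion (-3.02) and Welsh Arabian Pony (-2.68) were lowest, with the donkey at -3.13, and the Arabian, Lusitano, Paso Fino and the breed mate lay between -0.99 and -0.65. At these loci 0% to 61.1% of the probes of the lowest animals were well above background in the red channel, so those values are bounds.

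**Figure D3:**
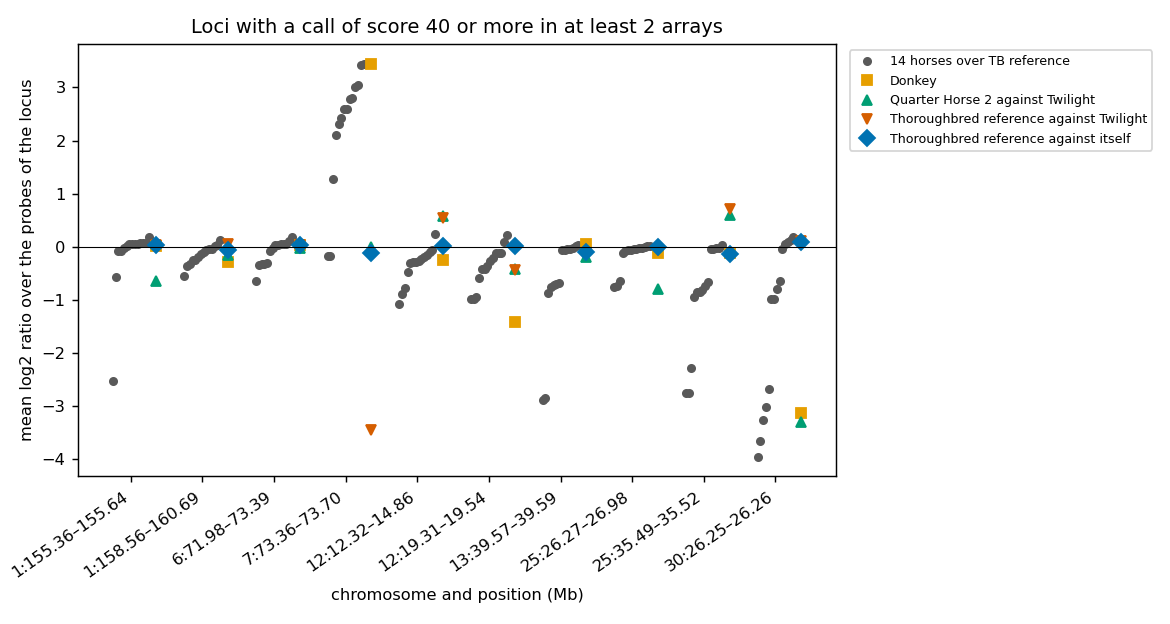
Mean log2 ratio (vertical axis) of each array at the loci called with an interval score of at least 40 in at least 2 arrays (horizontal axis, chromosome and position in Mb). Grey points are the 14 horses, sorted by value at each locus, and the coloured symbols the single arrays; at chromosome 13:39573372-39594524 the horses fall at -2.89 to -2.84, -0.87 to -0.69 and close to 0.

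The Thoroughbred was set against Twilight to show which differences belong to the reference animal itself. A difference of that animal turns sign in the red channel only if Twilight differs from it in the same direction as the horses do. Where Twilight shares its copy number or lies beyond it, the sign need not turn. At chromosome 3:43548122-43617913, for example, the horses averaged -0.52 and the self comparison lay at -0.0013, yet the Thoroughbred over Twilight kept the sign at -0.38. This array gave 281 calls, 175 gains and 106 losses, and 35 gains and 92 losses were left without calls over same-direction calls of the self comparison. Its strongest loss was the chromosome 7 interval at 73361042-73699307, followed by chromosome 7:74893714-74894512 (-1.80), chromosome 20:27781720-27782701 (-1.62), chromosome 12:19310505-19577504 (-0.46) and chromosome 5:37888905-37954145 (-0.84). Its strongest gains were chromosome 12:12682006-14871949 (0.54) with the adjoining 12315822-12681842 (0.62), chromosome 20:24252156-24556207 (1.60), chromosome 8:641099-697140 (0.79) and chromosome 10:14122621-14215780 (0.50). At all of these except chromosome 12:19310505-19577504 the median of the 14 horses had the opposite sign. A total of 164 regions were called the same way in at least 10 horses, and 23 of them (14.0%, exact binomial 95% interval 9.10 to 20.3) had the opposite sign in the Thoroughbred against Twilight (exact binomial test, two-sided, p = 6.824e-22). At a score of 8 the share was 32.7% (18 of 55, interval 20.7 to 46.7, exact binomial p = 0.0145). With the self comparison subtracted and regions called anew, 21 of 28 such regions (75.0%) had the opposite sign (exact binomial p = 0.0125). The direction thus turned with this subtraction. It also turned, without passing the threshold, without the Hanoverian and Curly arrays, where 10 of 12 horses were needed (17 of 25, exact binomial p = 0.108), without calls over same-direction calls of the self comparison (21 of 32, exact binomial p = 0.110) and in the regions called in all 14 horses (4 of 7, exact binomial p = 1). Regions are not independent replicates, so these binomial p-values can be too small. Spearman's rho across regions was 0.495, but -0.0267 at a score of 8, -0.715 with the self comparison subtracted and -0.645 without the Hanoverian and Curly arrays.

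**Figure D4:**
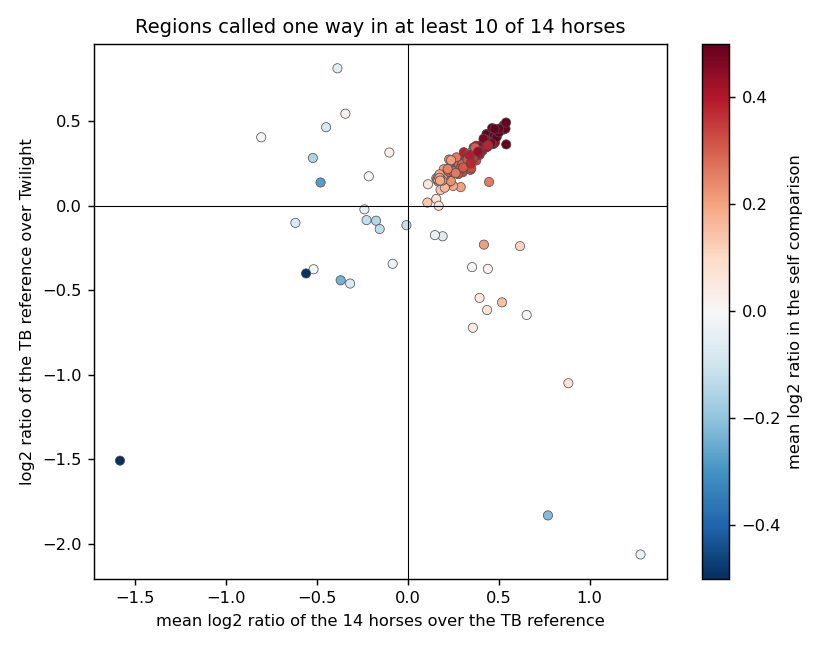
Each point is 1 of the 164 regions called the same way in at least 10 of 14 horses, by the mean log2 ratio of the horses over the Thoroughbred (horizontal axis) and the log2 ratio of the Thoroughbred over Twilight (vertical axis), coloured by the self comparison. Points in the upper left and lower right have opposite signs (23 of 164).

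Blocks of 10 consecutive probes were tested in place of genes for a mean of the 14 horses away from 0. Of 40013 blocks, 412 were higher and 227 lower in the horses than in the Thoroughbred (limma, adjusted p under 0.05 and a mean of at least 0.3 in size). The 10 highest blocks all lay at chromosome 7:73361042-73678939, with means of 2.41 to 3.43. Much of the green signal of the Thoroughbred there was not well above background, so these means and their errors rest on bounds and their order is not read. The block at chromosome 7:73626261-73646532 averaged 2.41 ± 0.32 (SE, higher in 12 of 14 horses, limma adjusted p = 7.88e-06). The lowest block, at chromosome 30:28077366-28090396, averaged -0.78 ± 0.28 (SE, lower in 14 of 14, limma adjusted p = 0.0225). It lay at -0.10 in the self comparison and -0.11 in the Thoroughbred against Twilight. Among the 10 lowest, chromosome 8:645427-657586 averaged -0.68 ± 0.16 (SE, lower in 14 of 14, limma adjusted p = 0.00175) and stood at 1.02 in the Thoroughbred against Twilight, and chromosome 12:14667251-14719880 averaged -0.75 ± 0.24 (SE, lower in 14 of 14, limma adjusted p = 0.0146). At chromosome 8:75722926-75723368, chromosome 5:41399889-41406044, chromosome 22:775296-780629 and chromosome 12:31756570-31765233 the horses averaged -0.70, -0.71, -0.73 and -0.78, and the self comparison lay as low (-0.84, -0.78, -0.75 and -0.83). Of the higher blocks, 347 (84.2%) reached 0.2 in the self comparison too, and 72 (31.7%) of the lower blocks lay at -0.2 or below there. With the self comparison subtracted, 139 blocks were higher and 191 lower.

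The horse set against Twilight gave 274 calls, 160 gains and 114 losses, of which 53 gains and 108 losses lay outside same-direction calls of the self comparison. Its strongest losses were chromosome 25:26353303-26980133 (-0.81), chromosome 1:155361070-155640247 (-0.66), chromosome 30:26250599-26262816 (-3.23, a bound), chromosome 1:158856693-159258786 (-0.78) and chromosome 3:43563028-43606174 (-0.88). Its strongest gains were chromosome 12:12568519-14781875 (0.62), chromosome 20:26266331-26538878 (0.44), chromosome 12:12464219-12568466 (0.67), chromosome 10:64980029-64982043 (0.97) and chromosome 1:139011183-139011657 (1.08). Its ratio minus that of the Thoroughbred against Twilight was set against each horse across 3288 regions. Its breed mate ranked 8 of 14, with r = 0.118 (0.213 and rank 4 with normexp), and the Andalusion ranked first, with r = 0.372; regions are not independent replicates and no p was computed. The Andalusion, Arabian and Welsh Arabian Pony ranked highest and had the smallest shares of calls over self-comparison calls (4.35%, 3.49% and 6.70%). With the self comparison subtracted, r ran only from 0.229 in the Hanoverian to 0.339 in the Andalusion. The ranking is therefore not read as likeness of animals.

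Pairs of horses whose breeds share a name or a history were compared with all other pairs, and neither difference passed the threshold. Across the 3288 regions, pairs among the Arabian, Shagya Arabian and Welsh Arabian Pony had a mean r of 0.533, against 0.643 in all other pairs, a difference of -0.110 (exact permutation test over all sets, two-sided, p = 0.6209). Pairs among the Andalusion, Lusitano, Paso Fino and Peruvian, breeds with Iberian ancestry, had a mean r of 0.604 against 0.642 (exact permutation test over all sets, two-sided, p = 0.8192). Pairs on the same slide had a mean r of 0.705 against 0.623 on different slides (permutation test, two-sided, p = 0.00984). Pairs from the same scan run, a split chosen after seeing the data, had a mean r of 0.771 against 0.630 (permutation test, two-sided, p = 0.00111). All pairs share the Thoroughbred reference, which raises every correlation, so only differences between pairs were compared. These can also follow how far each array carries the self-comparison profile, which was small by calls in the Arabian, Andalusion and Welsh Arabian Pony. The Arabian and Shagya Arabian had r = 0.375, the Paso Fino and Shagya Arabian 0.919. The Arabian and Welsh Arabian Pony shared a scan run, as did the Andalusion and Lusitano. The differences are therefore not read as likeness of animals. After the self comparison was subtracted, both breed differences turned positive (0.067 and 0.062), without passing the threshold.

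The donkey, another species of the horse genus, was set against the Thoroughbred to show differences between species. It gave 689 calls, 172 gains and 517 losses, and 203 gains and 237 losses with normexp background correction. Of all its calls 215 reached 1 in size, against 4 to 30 in the horses. Besides the chromosome 7 interval, its strongest gains were chromosome 3:36799446-36981254 (4.89 ± 0.36, SD over 51 probes), chromosome 20:26300722-26489246 (1.96 ± 0.75, SD over 146 probes), chromosome 1:66631919-66710963 (2.80) and chromosome 8:89008844-89019049 (1.02). At the chromosome 3 locus the 14 horses lay between 0.01 and 0.14. Its strongest losses were chromosome 5:16270591-16745336 (-2.39, 59 probes), chromosome 5:21922516-21950293 (-3.02), chromosome 29:78926-251970 (-2.55), chromosome 14:130169-516859 (-2.36) and chromosome 12:19310579-19542667 (-1.40). A loss here is a loss of signal, and what lowers it was not measured.

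In the test of blocks, 530 were higher and 1372 lower in the donkey than in the 14 horses (limma, adjusted p under 0.05, difference of at least 0.3 in size). Chromosome 3:36877828-36917636 was higher by 4.99 ± 0.09 (SE, limma adjusted p = 4.5e-20), and chromosome 20:26388648-26417995 by 2.17 ± 0.21 (SE, limma adjusted p = 3.09e-07). At chromosome 16:40031943-40033361 the donkey lay at 1.95 and the horses at -0.65, a difference of 2.60 ± 0.35 (SE, limma adjusted p = 4.73e-05). The lowest block, at chromosome 5:21931654-21945730, differed by -3.92 ± 0.25 (SE, limma adjusted p = 4.43e-10). It was followed by chromosome 5:16305907-16306509 (-3.60 ± 0.12), chromosome 5:21922910-21931606 (-3.56 ± 0.21) and chromosome 29:78926-111507 (-3.41 ± 0.12). Lower blocks made up 3.43% of all blocks, from 1.75% on chromosome 18 to 7.73% on chromosome 31; the difference between chromosomes was not tested. The lone donkey is assumed to vary like the horses, and with each horse in its place 0 to 61 blocks were called. Its probe-to-probe noise was 0.335, above the 0.297 of the noisiest horse array, the Welsh Arabian Pony. The standard errors and p-values therefore rest on the spread of less noisy arrays and can be too small. With scan run as a fixed block the donkey was set against the Gypsy Vanner alone, the only horse in its scan run, so the counts of that fit are not read. With normexp background correction 170 blocks were higher and 149 lower. The normexp offset changes ratios by construction, drawing them toward 0 before centring, while the size cutoff of 0.3 stayed. The normexp counts are therefore not read as instability alone.

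The level of the X chromosome shows whether the animals of an array differ in their number of X chromosomes. The median log2 ratio of X probes was -0.82 in the Andalusion, -0.78 in the Curly and -0.69 in the Welsh Arabian Pony, and -0.84 in the donkey. The other 11 horses lay within 0.05 of 0, as did the Thoroughbred against itself (0.03), the Thoroughbred against Twilight (0.01) and the horse set against Twilight (0.02). With normexp background correction the Andalusion moved to -0.46, the Curly to -0.50, and the Welsh Arabian Pony and the donkey to -0.41 each. The normexp offset of 50 draws ratios toward 0 by construction before centring, more so at low signals. Median background-subtracted red signals were 68.5 in the donkey, 80.0 in the Welsh Arabian Pony, 92.1 in the Andalusion and 117 in the Curly. These smaller sizes are therefore not read as instability of the X levels, and the share due to the offset was not tested.

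**Figure D5:**
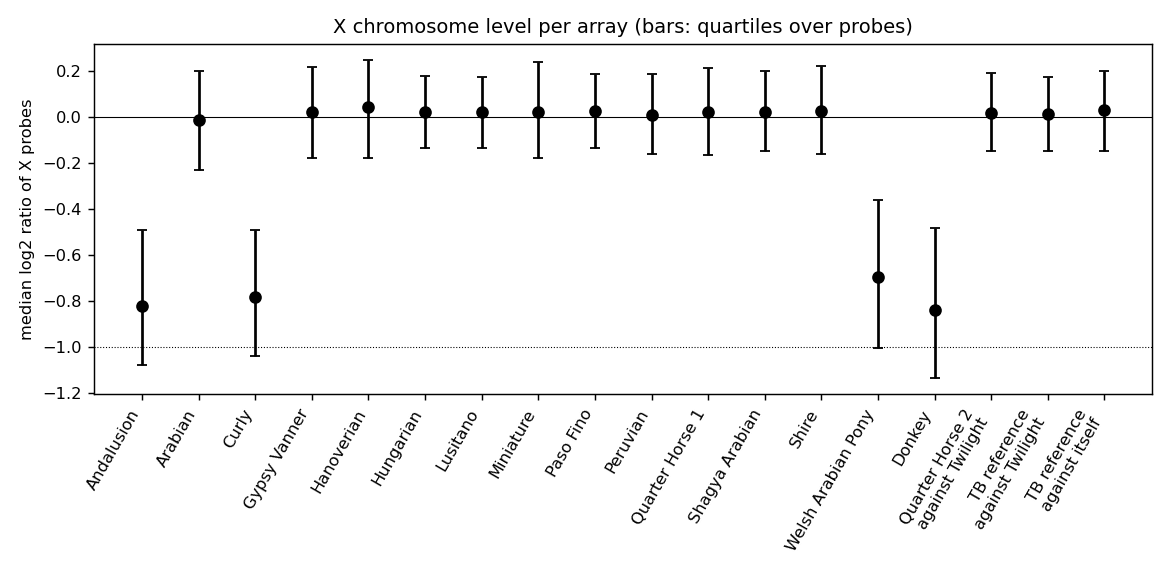
Median log2 ratio of X probes (vertical axis, points) in each array, with bars from the first to the third quartile over probes. The Andalusion, Curly, Welsh Arabian Pony and donkey lie between -0.84 and -0.69, and the other arrays near 0.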

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

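The result in this part was singled out by comparing signs after the values were seen. At chromosome 5:21915310-21950293 all 14 horses lay above the Thoroughbred, between 0.28 and 1.11 with a mean of 0.62 ± 0.26 (SD, n = 14), and the donkey lay on the other side at -2.787. The difference over the whole region was not tested. A block inside it, at chromosome 5:21922910-21931606, differed by -3.56 ± 0.21 (SE, limma adjusted p = 8.87e-11). The Thoroughbred against Twilight lay at -0.24 there and the self comparison at 0.12. No technical or biological explanation was tested for this locus.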

How the results depend on the processing

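The probe length corrections, the removal of calls over self-comparison calls, the scan runs, the fixed blocks and the fits without the Hanoverian and Curly were chosen after seeing the data. Of 179 alternative values, 130 kept their direction and side of the threshold or stayed within the set range, 42 moved and 7 reversed. Of the 130, 26 used the value table, whose ratios are those of the scanner files, so they say nothing about stability. The cause of a change was not tested unless the alternative itself gives it. A score of 8, a size of 0.5 and a hidden Markov model change what counts as a call by construction. Normexp, with its offset of 50, draws ratios toward 0 by construction, more so at low signals, while the size cutoff of 0.3 stayed. Fewer or more calls or blocks and smaller X levels with normexp can come from the offset, and how much does was not tested.

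Calls of the 14 horses (9580) became 4144 with a score of 8, 6181 with a size of 0.5, 6308 with normexp, 3808 with the self comparison subtracted, 15331 with the hidden Markov model, 6070 with the probe length correction and 4068 with that correction and the self profile. Regions (3288) became 1260 with a score of 8, 1622 with normexp, 2012 with the self comparison subtracted, 5610 with the hidden Markov model, 1953 with probe length and 1618 with probe length and self profile. Regions in at least 10 horses (171) became 59 with a score of 8, 55 with a size of 0.5, 31 with the self comparison subtracted, 80 with probe length, 32 with probe length and self profile, 38 without self-comparison calls, 108 with 50% reciprocal overlap and 30 without the Hanoverian and Curly, where 10 of 12 horses were needed. Calls of the self comparison (497) became 137 with a score of 8, 228 with a size of 0.5, 885 with the hidden Markov model and 228 with probe length. Calls of the Thoroughbred against Twilight (281) became 112 with a score of 8, 134 with a size of 0.5, 460 with the hidden Markov model, 113 with probe length and self profile and 127 without self-comparison calls. Calls of the horse set against Twilight (274) became 99, 133 and 433 under a score of 8, a size of 0.5 and the hidden Markov model, 427 with normexp, 142 with probe length and self profile and 161 without self-comparison calls. Calls of the donkey (689) became 280 with a score of 8, 440 with normexp (46.1% gains, against 24.96%) and 1164 with the hidden Markov model. With normexp, gains made up 98.6% of the self comparison's calls, against 54.7% (83.9% with a score of 8, 67.1% with probe length, 44.3% with the hidden Markov model), 85.5% of those of the horse set against Twilight, against 58.4%, and 83.3% of those of the Thoroughbred against Twilight, against 62.3%. Gains fell to 27.6% and 32.9% of the calls of the Thoroughbred and the horse set against Twilight, and to 50.3% of those of the 14 horses, without self-comparison calls. With probe length and self profile the first pair were 34.5% and 43.0%, and with the self comparison subtracted 76.0% and 74.3%. Centring on all probes moved no such share by over 10 percentage points.

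Blocks away from 0 in the horses (639) became 378 with normexp (147 higher, 231 lower), 330 with the self comparison subtracted, 20541 with no minimum size and 314 with probe length and self profile. Blocks of the donkey (1902) became 319 with normexp and 889 with medians over probes. With slide as a random or fixed block and with scan run as a random block the total stayed within 1.5 times. Higher blocks (530) became 888 with scan run as a random block. Scan run as a fixed block left only the Gypsy Vanner to compare with the donkey, so that count is not read. The share of widely called regions with the opposite sign in the Thoroughbred against Twilight (14.0%) was 32.7% with a score of 8 and reversed to 75.0% with the self comparison subtracted, 75.9% with probe length and self profile, 65.6% without self-comparison calls, 68.0% without the Hanoverian and Curly and 57.1% in regions called in all 14 horses. The similarity differences of the Arabian-named and Iberian-descended horses (-0.110 and -0.038) reversed to 0.067 and 0.062 with the self comparison subtracted. The correlation of the horse set against Twilight with its breed mate (0.118) moved to 0.256 with a score of 8, 0.283 with the self comparison subtracted and 0.223 with probe length and self profile, at ranks 8, 9 and 10, and stood at 0.213 and rank 4 with normexp. With normexp the X level moved past the set range of 0.335 to -0.46 in the Andalusion and -0.41 in the donkey. It stayed within that range at -0.50 in the Curly and -0.41 in the Welsh Arabian Pony. Not run were 10 probes per gene, since every block has 10, subtraction of the self comparison from itself, and gene list enrichment. Weak red signal, lowest in the donkey with 87.3% of probes well above background, limits how far a loss can be measured.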

Other observations

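The loci in this paragraph were chosen after their values were seen, from calls with an interval score of at least 40. Chromosome 22:38814173-38817519 (76 probes within 3.35 kb) lay between -1.03 and -0.80 in the Peruvian, Miniature, Lusitano, Andalusion, Curly and Arabian and at -0.97 in the donkey, between -0.46 and -0.18 in the Hungarian, the Hanoverian, the Welsh Arabian Pony and the breed mate of the horse set against Twilight, and between -0.03 and 0.04 in the other 4 horses. Chromosome 20:28369512-28574315 (154 probes) was low in the Lusitano, at -0.82, with the other horses between -0.16 and 0.08. Chromosome 5:38643062-38643717 (12 probes) was low in the Miniature, at -3.52 (a bound, with 33.3% of its red probes well above background), with the other horses between -0.22 and 0.07. Chromosome 5:77326088-77327014 (9 probes) lay at -4.23 in that breed mate, with 0% of its red probes well above background, and at -1.05, -0.87 and -0.81 in the Welsh Arabian Pony (44.4%), Gypsy Vanner (66.7%) and Shire. Chromosome 1:158563669-160690242 (460 probes) was lowest in the Gypsy Vanner (-0.55) and the Shagya Arabian (-0.37). Chromosome 12:19310579-19542667 (125 probes) ran from -0.99 in the Gypsy Vanner to 0.21 in the Hungarian, with the donkey at -1.41.

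Of the tests below, only that of sequence divergence in the donkey was set before its result was seen; all the others were chosen afterwards. Regions called the same way in at least 10 horses could come from the Thoroughbred reference or from dye and probe effects. Regions are not independent replicates: neighbouring regions are counted singly, and each test rests on the values of 1 array. The exact binomial p-values below can therefore be too small. Of 145 gained regions, 10.34% turned sign in the Thoroughbred against Twilight (exact binomial p = 4.814e-24). Regions that kept their sign do not decide on the reference animal, because the sign turns only where Twilight differs from it as the horses do. In the self comparison 73.1% of the 145 reached 0.2 with the same sign (exact binomial p = 2.403e-08), as dye and probe effects would give. Without the Hanoverian and Curly arrays only 12 regions were gained in at least 10 of the other 12 horses, all of them sharing probes with the 145, and 83.33% of these turned sign (exact binomial p = 0.03857) while 16.67% reached 0.2 in the self comparison (exact binomial p = 0.03857), so for them the reference animal is a candidate explanation and dye and probe effects are argued against for most. The cutoff stayed at 10 with fewer arrays, so these regions are also more strictly selected. No other pair of arrays was left out, so the change is not tied to the Hanoverian and Curly. Of 19 lost regions, 21.05% reached 0.2 in size with the same sign in the self comparison (exact binomial p = 0.01921), which argues against dye and probe effects for most of these, and 42.11% turned sign (exact binomial p = 0.6476), so the reference animal stays open for them. Of 16 gained regions called anew with the self comparison subtracted, 13 shared probes with the 145 and 81.25% turned sign (exact binomial p = 0.02127), and of 15 called anew with probe length and self profile removed, 15 shared probes with the 145 and 100% turned sign (exact binomial p = 6.104e-05); no biological explanation other than the reference animal was tested.

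The number of calls per horse array may follow array quality. Across 14 arrays it rose with the share of variance that goes with probe length (Spearman's rho = 0.833, permutation p = 0.00029, adjusted 0.000725; Pearson's r = 0.854, p = 0.00063, adjusted 0.00158, and 0.692 without the Hanoverian and Curly). It also rose with red signal over noise (rho = 0.7231, permutation p = 0.0047, adjusted 0.00588; r = 0.579, p = 0.024, adjusted 0.03, and 0.7001 without the Paso Fino and Hungarian). Adjustment was by Benjamini-Hochberg over the 5 relations computed at each level, and with ranks or values centred on each slide, which holds 3 or 4 horse arrays and so gives no value of its own, neither passed the threshold: probe length gave rho = 0.655 (exact permutation within slides, p = 0.0566, adjusted 0.0944; r = 0.732, p = 0.0814, adjusted 0.136), and red signal over noise, whose sign differed between slides, rho = 0.581 (p = 0.121, adjusted 0.152; r = 0.363, p = 0.405, adjusted 0.506). Across the means of the 8 scan runs rho was 0.976 for probe length (exact permutation p = 0.000397, adjusted 0.000992; r = 0.928, p = 0.000124, adjusted 0.000496) and 0.833 for red signal over noise (exact permutation p = 0.0154, adjusted 0.0256; r = 0.565, p = 0.156, adjusted 0.195), so array quality, other differences between batches and true differences between animals all stay open.

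Losses outnumbered gains in the donkey, 517 to 172 (237 to 203 with normexp background correction and 176 to 104 at a score of 8), which could come from sequence divergence of single probes or from weak red signal. For divergence, the ratio of probes below -0.8 to probes above 0.8 outside calls had to exceed that of all 14 horses, and a ratio under their median was set beforehand to count against it. The ratio was 2.178, under the median of 2.383 and thus past the bound set beforehand, but by less than the horses' SD of 0.823, a margin added after the value was seen; both tails were wider in the donkey than in any horse (4.21% of probes below -0.8 against at most 2.11%, and 1.93% above 0.8 against at most 1.11%), so divergence was neither supported nor excluded. Across the horses the percent of losses fell with red signal over noise (rho = -0.7934, permutation p = 0.00131, adjusted 0.00218; r = -0.715, p = 0.00643, adjusted 0.0107, and -0.636 without the Paso Fino and Hungarian), also when centred on each slide (rho = -0.906 and r = -0.856, exact permutation within slides, p = 4.82e-05 for each, the smallest they can give, adjusted 0.000241), while across the means of the 8 scan runs rho was -0.619 (exact permutation p = 0.115, adjusted 0.144; r = -0.742, p = 0.0349, adjusted 0.0582). The share moved with the number of gains (rho = 0.864, permutation p = 0.00016, adjusted 0.000725; r = 0.868, p = 0.00011, adjusted 0.00055, and 0.927 without the Paso Fino and Hungarian; within slides rho = 0.768, exact permutation p = 0.0509, adjusted 0.0944), and the number of losses showed no relation that passed the threshold (rho = 0.0989, permutation p = 0.739, adjusted 0.739; r = 0.0583, p = 0.880, adjusted 0.880, and 0.254 without these 2; within slides rho = -0.212, exact permutation p = 0.404, adjusted 0.404), so whether the weak red signal of the donkey, at 12.6 the lowest over noise, bears on its losses stays open, as do copy number differences between the species, which were not tested.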
